A study of Mus musculus with 18 samples.

How the data were processed

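RNA was measured in 18 libraries from cells derived from mouse embryonic stem cells (strain C57BL/6 per the labels), in 6 groups of 3 libraries. The groups are neuromesodermal progenitors (NMPs, cells that can give rise to spinal cord and to paraxial mesoderm) of wild-type and of Hoxb1-null genotype, and neural progenitors with or without Hoxb1, each in the presence or absence of SAG, a Smoothened agonist that activates hedgehog signalling. The neural progenitors labelled as expressing Hoxb1 were the ones given doxycycline (DOX), so Hoxb1 and doxycycline cannot be told apart in these libraries. Whether the 3 libraries of a group come from separate differentiations or from 1 culture is not given in the sources used here. Whether all neural progenitor cultures came from the same line or clone is not given either, so that a difference between lines is not separated from Hoxb1 or SAG. Wild-type and Hoxb1-null NMPs differ in genotype, and any further difference between their lines is not separated from the loss of Hoxb1. If the libraries of a group are technical, the spread between them understates that between cultures.

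Per the labels, polyadenylated RNA was selected from total RNA, strand-specific libraries were made with a directional kit and 15 PCR cycles, reads were called with bcl2fastq 1.8.2, and reads per gene were counted with featureCounts 1.4.6 on the mm10 genome. The deposited values are raw counts per Ensembl gene, with no normalization by the authors, for 37224 genes, and the same table gives exon coordinates and another column, the summed exon length in bases, which was not used in the tests. The aligner, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Symbols were matched by Ensembl ID for 35449 genes and were missing for 1775. Gene types were read from GENCODE vM21, which may differ from the annotation the authors used.

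Library numbers in the labels run from 2533 to 2538 for the neural progenitors with SAG, from 7390 to 7395 for those without SAG, and from 8085 to 8090 for the NMPs. Within each of these ranges both Hoxb1 states are present. The comparisons of SAG with no SAG and the difference of the Hoxb1 effects run across ranges and are therefore confounded with the library set. Residuals of libraries with the same replicate number were not alike throughout any pair of groups, and the main analysis has no replicate term.

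Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group at its defaults, libraries were scaled with TMM factors, and dispersions were estimated with estimateDisp. Tests were quasi-likelihood F-tests (glmQLFit with robust estimation, glmQLFTest), with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The 6 NMP libraries were fitted alone (15032 genes, common biological coefficient of variation 3.82%, 4 residual degrees of freedom). The 12 neural progenitor libraries were fitted together with 1 mean per group (16238 genes, 2.91%, 8 residual degrees of freedom). TMM factors lay between 0.972 and 1.03.

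6 comparisons were made. These were Hoxb1-null minus wild type in NMPs, Hoxb1 minus no Hoxb1 in neural progenitors without SAG and with SAG, the difference of these effects, and SAG minus no SAG without and with Hoxb1. Levels are given as CPM (counts scaled to the effective library size, TMM factors included, as drawn in the plots) as mean ± SD of 3 libraries. The standard error (SE) of a log2 fold change is the change divided by the square root of its F statistic. It comes from the test and is not a Wald error, so the errors of separate comparisons do not combine into that of their difference. Where a group held no count of a gene, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its 95% exact binomial (Clopper-Pearson) counting interval. Intervals and bounds cover counting error only, because reads carry no molecular identifiers.

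The comparisons, the tests, the 35 gene lists, the rule for naming genes and all alternative settings but 1 were fixed before the data were examined. The rule names Hoxb1 in every comparison. It adds the 5 genes with the largest rise and the 5 with the largest fall (3 and 3 for the difference of effects and the SAG comparisons) among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups. Symbols of predicted genes, RIKEN clones and pseudogenes were left out. From each list, up to 2 called members with at least 1 CPM and the largest change were named, lists being taken in order of their test, until 30 genes were named. 12 genes were named whatever their value, of which 1 is not reported here, nor is 1 gene seen after the fits. The other 11 are Hoxb2, Hoxa2, Gli1, Ptch1, T, Sox2, Tbx6, Cdx2, Nkx2-2, Neurog2 and Hes5.

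Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, where at least 3 members were tested, with adjustment over the lists of a comparison. Camera was then run with a correlation estimated from the data, and fry was run as a test without comparison to other genes. Camera asks whether a list moved more than the other genes.

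The procedure was tested on simulated data before it was applied. It recovered 89% to 94.9% of simulated 2-fold changes in the 5 comparisons of groups and 73.2% in the difference of effects, where the limit set in advance for going on was lowered to admit this value. At 1.5-fold it recovered 79.4% to 82.7% and 70.4%. False calls were 5.11% to 8.56% of all calls, and each of the 5 raised lists and 0 of the 15 unchanged lists were called by camera in every simulated comparison. Genes were simulated independently of each other and lists were drawn at random. The simulation therefore does not test list calls at the preset correlation where the genes of a list are correlated. It held 97 to 100 changed genes at each fold, in both directions, whereas the real comparisons called 28.8% to 72.7% of tested genes. Recovery, false calls and scaling were thus not tested at such shares of changed genes.

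Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0 with its defaults, limma-voom, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, an added fold limit, an adjusted p under 0.01, each library left out in turn, a replicate block, a fit of only the 6 libraries compared, and a fit of all 18 libraries. A count without genes of chromosomes 8, 11 and Y was added after seeing the data. Reads, alignments and splice variants were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.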

Results

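The series asks what Hoxb1, a homeodomain transcription factor of the anterior Hox genes, does in 2 contexts, by RNA sequencing of wild-type and Hoxb1-null NMPs and of neural progenitors with and without induced Hoxb1. Each of the 6 groups held 3 libraries. Total counts per library were 16523276 to 21141058 in wild-type NMPs and 16836409 to 19136064 in Hoxb1-null NMPs. In neural progenitors they were 13589876 to 13976829 without Hoxb1 or SAG, 13301476 to 14505711 with Hoxb1, 22682012 to 26974315 with SAG, and 22610407 to 24488882 with Hoxb1 and SAG. The sets with SAG were counted more deeply than those without. Mitochondrially encoded genes took 0.865% to 1.3% of counts as group means. The first principal component of the neural progenitors (61.4% of the variance) separated libraries with and without SAG, and the second (20.9%) separated libraries with and without Hoxb1. In NMPs the first component (63.7%) separated the genotypes.

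Hoxb1 (ENSMUSG00000018973, mm10 chromosome 11, 96365752 to 96368256, plus strand) was measured in every group. In wild-type NMPs it stood at 237 ± 13.7 CPM (SD, n = 3) and in Hoxb1-null NMPs at 14.2 ± 0.811 CPM, 16.7-fold lower (log2 change -4.06, SE 0.0594, edgeR adjusted p = 2.51e-23), with 234 to 291 counts per null library. Neural progenitors without Hoxb1 had 0.37 ± 0.298 CPM (1 to 9 counts per library), and those with Hoxb1 had 336 ± 17.2 CPM. With SAG the levels were 0.475 ± 0.0684 CPM (11 or 12 counts) and 614 ± 19.2 CPM. The induced level was higher with SAG than without (log2 change 0.87, SE 0.0371, adjusted p = 2.11e-19), while the Hoxb1 effect itself did not pass the test of a difference by SAG (0.52, SE 0.483, adjusted p = 0.441).

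**Figure D1:**
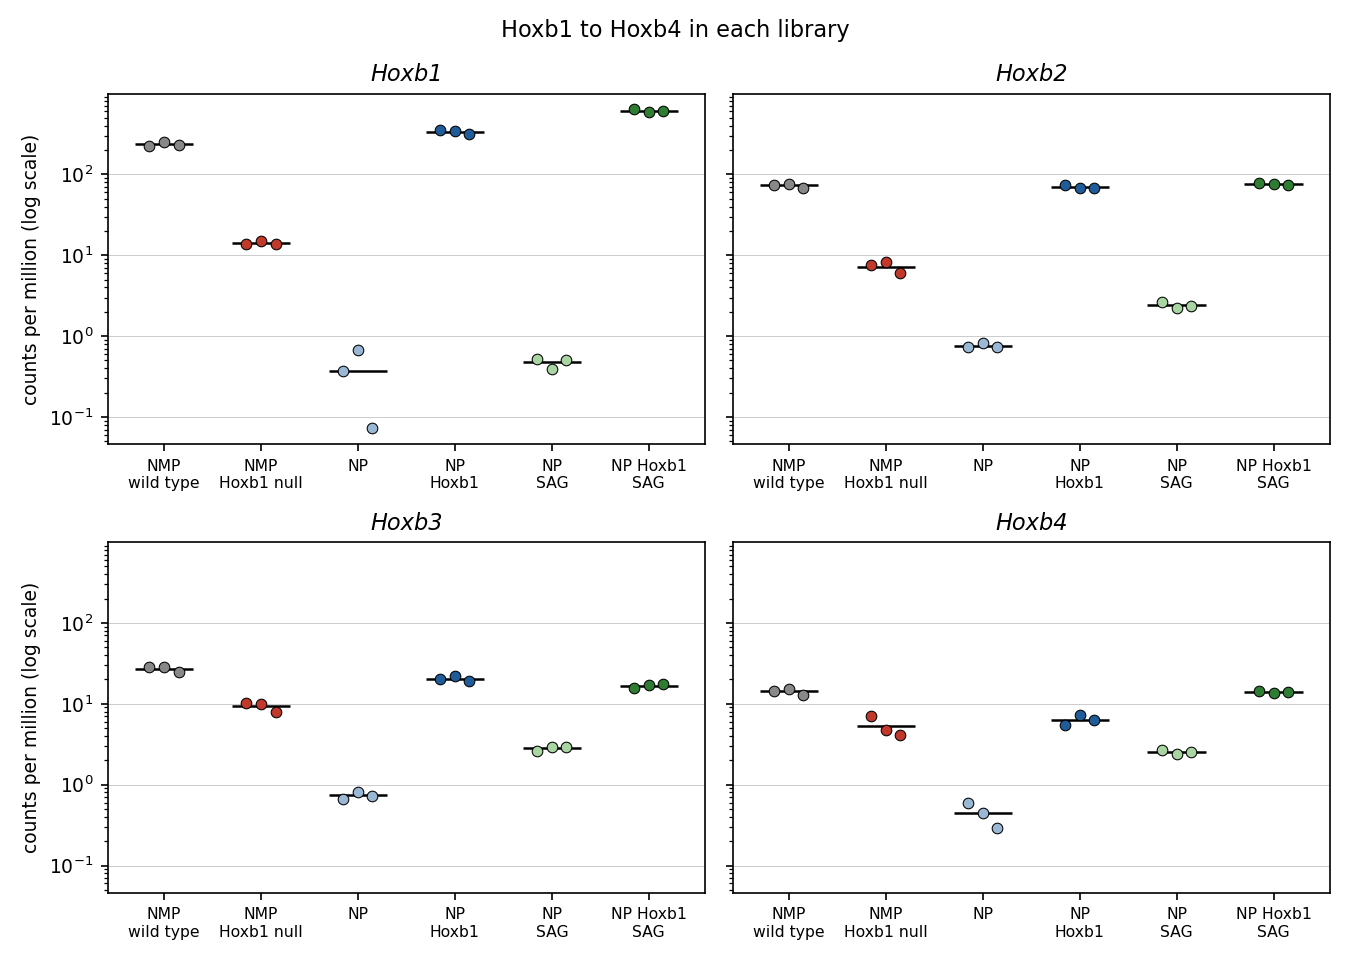
CPM of Hoxb1, Hoxb2, Hoxb3 and Hoxb4 (log axis) in each of the 18 libraries of the 6 groups, with points for libraries and lines for group means (Hoxb3 and Hoxb4 were chosen after their values were seen). Hoxb1 lies at 237 CPM in wild-type and 14.2 CPM in null NMPs, and Hoxb2 at 73 and 7.24 CPM.

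In NMPs, Hoxb1-null cells had lower levels of several other anterior Hox genes. Hoxb2, the neighbour of Hoxb1 in the cluster, fell 10-fold (73 ± 4.16 to 7.24 ± 1.11 CPM, log2 change -3.33, SE 0.0819, adjusted p = 7.31e-19, n = 3 and 3). Hoxa2 on chromosome 6 stood at 4.17 ± 0.319 CPM in wild type and 4.27 ± 0.543 CPM in null cells and was not called (adjusted p = 0.878). Fgf8, a growth factor of the tail bud, fell from 66.5 ± 2.5 to 27.7 ± 6.99 CPM (adjusted p = 0.00187). Olig2, a transcription factor of motor neuron progenitors, rose from 4.4 ± 0.591 to 10.7 ± 1.36 CPM (adjusted p = 1.05e-07). Among 15032 tested genes, 2244 were higher and 2083 lower in null cells. Of these, 326 and 104 differed at least 2-fold. A difference between the wild-type and null lines other than Hoxb1 is not separated from the loss of Hoxb1 in these counts.

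The lists of Hox groups 1 to 4 and 5 to 9 were lower and that of groups 10 to 13 higher in null cells at the preset correlation, and 0 of these 3 calls held with an estimated correlation. Of Hox groups 1 to 4, 8 of 11 tested members fell, Hoxb1 among them, and none rose (median log2 change -0.63, camera adjusted p = 5.82e-06, and adjusted p = 0.361 with an estimated correlation). Of groups 5 to 9, 9 of 13 fell and none rose (median -0.78, adjusted p = 0.000241, and adjusted p = 0.461 with an estimated correlation). Hoxb5 fell from 2.94 ± 0.991 to 0.74 ± 0.197 CPM and Hoxb6 from 4.21 ± 0.781 to 1.18 ± 0.45 CPM. Of groups 10 to 13, 3 of 4 rose and none fell (median 0.92, adjusted p = 0.0128, and adjusted p = 0.363 with an estimated correlation), among them Hoxa11 (log2 change 1.73, 0.438 to 1.45 CPM) and Hoxc13 (1.14, 2.8 to 6.08 CPM). All 8 tested Hoxb genes of groups 2 to 9 fell (median log2 change -1.48), compared with 8 of 15 tested genes of groups 1 to 9 in the other clusters (median -0.44), a split made after the values were seen. Genes other than Hox genes within 1 Mb of Hoxb1 had a median change of 0.02 over 39 genes, with Skap1, the nearest tested one past Hoxb1, the lowest (-1.16, adjusted p = 0.000413).

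Most tested NMP markers were lower in null cells. Of 14 tested NMP genes, 11 fell and 1 rose (adjusted p = 0.000694, and adjusted p = 0.361 with an estimated correlation). Fgf17 fell by 0.91 on the log2 scale (SE 0.0911) and Cdx2, a caudal homeobox factor that activates posterior Hox genes, by 0.46 (SE 0.0674, adjusted p = 7.1e-05). T (brachyury), a mesoderm determinant, decreased by 0.11 (SE 0.0398, adjusted p = 0.0358), a call lost with upper-quartile scaling (adjusted p = 0.0727), with the stricter filter (0.0716) and without wild-type replicate 2 (0.24) or 3 (0.164) or null replicate 1 (0.102) or 2 (0.106). Of 15 presomitic and somitic genes, 6 fell, 2 rose and 7 were not called (mean log2 change -0.06, adjusted p = 0.0292, and adjusted p = 0.461 with an estimated correlation). Tbx6, which specifies paraxial mesoderm, fell from 185.5 ± 10.3 to 140.8 ± 6.9 CPM (adjusted p = 8.51e-07). Sox2, a neural progenitor factor, rose from 12.5 ± 1.02 to 15.3 ± 1.58 CPM (adjusted p = 0.023). That call was lost with DESeq2 (adjusted p = 0.0955) and without wild-type replicate 2 (0.149) or 3 (0.0621) or null replicate 1 (0.127).

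Several lists of other cell states were higher in null cells. Pluripotency genes rose in 8 of 11 members and fell in none (median log2 change 0.63, adjusted p = 2.83e-05, and adjusted p = 0.34 with an estimated correlation). Tfcp2l1 was at 14.1 ± 0.346 CPM in wild type and 28.4 ± 0.463 CPM in null cells and Dppa5a at 1.99 and 4.14 CPM. Ventral neural tube genes rose in 5 of 8 (adjusted p = 0.0101), dorsal and intermediate neural tube genes in 5 of 9 (0.0191), proneural genes in 3 of 6 (0.0105), and endoderm genes in 4 of 7 (0.0183), with no member falling in these 4 lists. Their adjusted p = 0.361, 0.34, 0.34 and 0.363 with an estimated correlation. Nkx2-9, a ventral neural tube factor, rose from 2.6 to 5.48 CPM and Neurod1, a neuronal differentiation factor, from 4.9 to 7.02 CPM. Ebf2 rose from 0.844 to 1.43 CPM (adjusted p = 0.0328), a call lost with DESeq2 (0.192) and without wild-type replicate 2 (0.185) or 3 (0.0716) or null replicate 1 (0.0951) or 2 (0.106). Lateral and intermediate mesoderm genes rose in 5 of 12 and fell in 1 (adjusted p = 0.0128, and adjusted p = 0.34 with an estimated correlation), among them Wt1 (log2 change 1.15) and Hand1 (0.67), both regulators of mesodermal organs.

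Stress and metabolic lists moved as well. Integrated stress response genes, targets of the amino acid and unfolded protein response, rose in 12 of 14 and fell in 1 (median log2 change 0.37, adjusted p = 2.89e-06, and adjusted p = 0.34 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, rose from 13.9 ± 0.703 to 36.6 ± 3.01 CPM, and Gdf15 rose from 0.422 to 1.05 CPM (adjusted p = 0.004, and 0.0521 with DESeq2). p53 targets rose in 7 of 12 and fell in 1 (adjusted p = 0.0186, and adjusted p = 0.461 with an estimated correlation). Hypoxia and glycolysis genes fell in 7 of 10 and rose in 1 (median -0.35, adjusted p = 0.0036, and adjusted p = 0.34 with an estimated correlation), as in Bnip3 (log2 change -0.94) and Pgk1 (-0.73). Mitochondrially encoded genes fell in 6 of 7 (adjusted p = 0.0128, and adjusted p = 0.462 with an estimated correlation). Mitochondrial mt-Co1 was at 2939 ± 56.1 CPM in wild type and 2276 ± 145 CPM in null cells and mt-Nd6 at 77.6 and 52.7 CPM. Null replicate 3 had a mitochondrial share of 0.792%, against 0.902% and 0.901% in null replicates 1 and 2, and its pairs differed by a chi-square per gene of 5.07 and 3.93, against 2.33 for the other null pair. Cell cycle genes fell in 6 of 19 (adjusted p = 0.0438, and adjusted p = 0.461 with an estimated correlation). Adjusted over the list alone, the counts of this comparison were the same for the Hox, NMP, presomitic, neural tube, proneural, stress response and p53 lists, while 1 more member rose in the pluripotency, endoderm and lateral mesoderm lists and 1 more fell in the hypoxia, mitochondrial and cell cycle lists.

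The largest changes by the rule lay partly outside these lists. Meg3, a maternally expressed imprinted RNA on chromosome 12, fell from 438 ± 7.88 to 33.9 ± 1.25 CPM (12.9-fold, adjusted p = 6.7e-25). Capn11, a calpain protease, fell from 13.1 ± 1.17 to 1.86 ± 0.269 CPM. Hoxb3os fell from 60.4 ± 2.49 to 5.7 ± 0.177 CPM, but it overlaps Hoxb2 and Hoxb3 and the strand setting of the counts is not given in the sources used here. The largest rises were in AA465934 (3.08 to 16.7 CPM), Fosb (3.27 ± 1.05 to 13.6 ± 4.34 CPM, adjusted p = 0.00838), Lox, a collagen crosslinking enzyme (3.53 to 10.7 CPM), Unc45b (4.19 to 12 CPM) and Hrk, a proapoptotic factor (7.17 to 19.5 CPM). Of the remaining genes named in advance, Gli1 rose (7.39 to 10.8 CPM, adjusted p = 0.000328), while Ptch1 (60.4 and 58.3 CPM, adjusted p = 0.54) and Neurog2 (0.465 and 0.773 CPM, 0.169) were not called. 19 lists were not called, the Notch pathway nearest (7 of 14 fell, adjusted p = 0.0596), and for 5 of these (hedgehog, hindbrain, Wnt, TGF-beta and BMP, and epithelium to mesenchyme) median, mean and test differed in sign. DESeq2 called 1426 genes higher, against 2244 with edgeR.

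In neural progenitors without SAG, the lists of anterior Hox and hindbrain genes were higher and that of forebrain and midbrain genes lower with Hoxb1 at the preset correlation, calls lost with an estimated correlation (adjusted p = 0.0515 for each of the 3). Hoxb2 rose from 0.76 ± 0.0498 to 69.5 ± 3.39 CPM (log2 change 6.51, SE 0.113, adjusted p = 2.58e-36, n = 3 and 3). Hoxa2, a hindbrain patterning gene, rose from 1.77 ± 0.408 to 21.6 ± 1.94 CPM (3.61, SE 0.146). Crabp1, a retinoic acid binding protein, rose 22.5-fold (16.6 ± 1.8 to 373.7 ± 8.14 CPM). Trim66 fell from 232.6 ± 42.6 to 7.45 ± 1.34 CPM and Atf5, a stress response transcription factor, from 793 ± 82.5 to 61.7 ± 2.04 CPM. Of 16238 tested genes, 3908 were higher and 3591 lower with Hoxb1, 462 and 493 of them at least 2-fold.

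Hox genes of groups 1 to 4 rose in 6 of 9 tested members, Hoxb1 among them, and fell in none (median log2 change 3.61, adjusted p = 0.000571, and adjusted p = 0.0515 with an estimated correlation). Groups 5 to 9, with 1 of 11 falling, and groups 10 to 13, with 0 of 8 called by edgeR, did not pass (adjusted p = 0.25 and 0.327), and 6 of the 8 latter genes had a group with 3 or fewer counts. Hindbrain genes rose in 7 of 9 and fell in 1 (adjusted p = 0.00397, and adjusted p = 0.0515 with an estimated correlation). Retinoid pathway genes rose in 6 of 11 and fell in 1 (median 1.25, adjusted p = 0.00112, and adjusted p = 0.0515 with an estimated correlation), among them Stra6, a retinol transporter (3.48 to 14.7 CPM). Hox cofactors rose in 6 of 9 and fell in 2 (adjusted p = 0.00825, and adjusted p = 0.115 with an estimated correlation). Forebrain and midbrain genes fell in 12 of 15 and rose in 1 (adjusted p = 4.73e-07, and adjusted p = 0.0515 with an estimated correlation). Six6, an eye field factor, fell from 16.9 ± 3.11 to 3.36 ± 0.522 CPM, while Pax8, also a gene of hindbrain interneurons, rose from 8.18 ± 0.899 to 41.8 ± 1.73 CPM.

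Lists of neuronal differentiation and of Notch signalling were higher with Hoxb1 in the absence of SAG at the preset correlation, and 0 of these calls held with an estimated correlation. Proneural genes rose in 9 of 11 and fell in 1 (adjusted p = 0.000571), postmitotic neuron genes rose in 12 of 17 and fell in 3 (0.00122), cranial and spinal motor neuron genes rose in 8 of 13 and fell in none (0.00397), and Notch pathway genes rose in 11 of 16 and fell in 1 (median 0.67, 0.000198). Their adjusted p = 0.0515, 0.115, 0.0515 and 0.0515 with an estimated correlation. Neurod4 rose from 4.48 to 21 CPM and Neurog3 from 1.91 to 6.17 CPM. Nefl and Ina, neurofilament and intermediate filament subunits, rose 2.2-fold and 2.21-fold. The Notch targets Hes5 (67.3 ± 2.79 to 145 ± 3.65 CPM) and Hey2 (2.28 to 6.03 CPM) rose as well. Neurog2 (38.8 ± 5.82 to 43.7 ± 2.2 CPM, adjusted p = 0.0444) lost its call with DESeq2 (0.107), upper-quartile scaling (0.0915), the stricter filter (0.0558), the 6 libraries alone (0.0825), all 18 libraries (0.0689) and without NP replicate 2 (0.156) or 3 (0.391), NP Hoxb1 replicate 1 (0.192) or 2 (0.0973), or any of 5 libraries with SAG (0.0541 to 0.0665), NP standing for neural progenitor. Mesenchyme and fibroblast genes rose in 8 of 11 (adjusted p = 0.000571, and adjusted p = 0.0575 with an estimated correlation), among them Col1a2 (132.6 ± 2.26 to 531 ± 14.8 CPM) and Postn (10.1 to 33.4 CPM), both of extracellular matrix. Cell cycle inhibitors rose in 7 of 10 and fell in 1 (adjusted p = 0.00824, and adjusted p = 0.0793 with an estimated correlation).

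Integrated stress response genes fell in 15 of 15 tested members (median log2 change -1.56, adjusted p = 1.02e-12, and adjusted p = 0.0515 with an estimated correlation). Among them Trib3 fell from 104 ± 12.3 to 9.35 ± 0.302 CPM, Chac1, a glutathione degrading enzyme, from 136.5 ± 5.7 to 18.3 ± 3.05 CPM, and Slc7a11, a cystine transporter, from 31.8 ± 3.52 to 3.99 ± 0.977 CPM. Mitochondrially encoded genes rose in 7 of 10 (adjusted p = 0.00723, and adjusted p = 0.24 with an estimated correlation).

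Several other signalling and early lineage lists were lower with Hoxb1 at the preset correlation, unlike the Notch and retinoid lists above. The 4 hedgehog feedback genes all fell (adjusted p = 0.00181, and adjusted p = 0.143 with an estimated correlation). Gli1 was at 157.7 ± 9.87 CPM without and 76.7 ± 1.89 CPM with Hoxb1, Hhip at 29.6 and 11.6 CPM, and Ptch1 fell by 0.48 on the log2 scale. Ventral neural tube genes fell in 7 of 10 and rose in 2 (adjusted p = 0.0334, and adjusted p = 0.177 with an estimated correlation), as in Nkx2-2 (8.3 to 2.86 CPM). FGF feedback genes fell in 8 of 10 and rose in 2 (adjusted p = 0.00122, and adjusted p = 0.219 with an estimated correlation). Spry1 and Dusp6, inhibitors of FGF signalling, were at 395 and 328 CPM without and 182 and 187 CPM with Hoxb1. Wnt feedback genes fell in 8 of 11 and rose in 2 (adjusted p = 0.00481, and adjusted p = 0.0515 with an estimated correlation). Pluripotency genes fell in 13 of 14 (median -0.99, adjusted p = 4.73e-07, and adjusted p = 0.143 with an estimated correlation), as in Klf2 (29.4 to 12.7 CPM) and Prdm14 (1.91 to 0.632 CPM). NMP genes fell in 8 of 12 and rose in 1 (adjusted p = 0.00175, and adjusted p = 0.0852 with an estimated correlation), among them T (12.7 ± 0.387 to 3.62 ± 0.0869 CPM), Fgf17 (4.01 to 1.2 CPM) and Cdx2 (36 counts over the group to 5). Endoderm genes fell in 4 of 7 (adjusted p = 0.00806, and adjusted p = 0.0901 with an estimated correlation), and immediate early genes fell in 7 of 10 and rose in 2 (adjusted p = 0.042, and adjusted p = 0.289 with an estimated correlation). Sox2 fell from 641 ± 35 to 544 ± 8.72 CPM, and Tbx6 was not called (2.79 and 3.76 CPM, adjusted p = 0.0551), although it passed with a replicate block (0.0465) and without replicate 1 of the Hoxb1 and SAG group (0.0456).

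Of the called lists of this comparison, 0 held when camera estimated the correlation (lowest adjusted p = 0.0515), against 21 with the preset correlation. Adjusted over the list alone, 13 Notch genes, 9 mesenchyme genes and 8 cell cycle inhibitors rose and 13 forebrain, 9 NMP and 9 Wnt feedback genes fell, and 1 Hox gene of groups 1 to 4 fell, with other counts of called lists unchanged. The 14 lists not called had adjusted p from 0.103 upward, and for glia median and mean differed in sign. Of the remaining genes with the largest rise, Tbx10 was at least 155-fold higher (0 counts without and 467 with Hoxb1), Mybpc1 rose from 1.77 to 120.9 CPM, and Hoxb3os, with the limit on strand given above, rose from 0.588 to 92.5 CPM.

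With SAG, cultures with Hoxb1 had higher motor neuron and Hox genes than cultures without. Tbx20, a T-box factor of cranial motor neurons, rose 17.2-fold (2.28 ± 0.165 to 39.2 ± 0.654 CPM, log2 change 4.10, SE 0.095, adjusted p = 3.62e-32, n = 3 and 3). Chat, the enzyme of acetylcholine synthesis, rose from 0.126 to 6.5 CPM. Nkx2-1, a ventral forebrain factor, fell from 104 ± 4.45 to 9.95 ± 1.56 CPM (log2 change -3.38, SE 0.063). Hes5 fell from 90.1 ± 2.4 to 23.6 ± 1.3 CPM. In total 3483 genes were higher and 3562 lower, 430 and 385 of them at least 2-fold. The median change of genes on chromosome 11 was -0.13, against -0.0022 to 0.021 for autosomes other than 8 and 11, and 633 of 1363 tested chromosome 11 genes were lower and 128 higher. Y-linked Ddx3y fell from 37.6 ± 1 to 11.2 ± 0.43 CPM. Without genes of chromosomes 8, 11 and Y, a count chosen after the values were seen, 3126 genes were higher and 2780 lower.

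**Figure D2:**
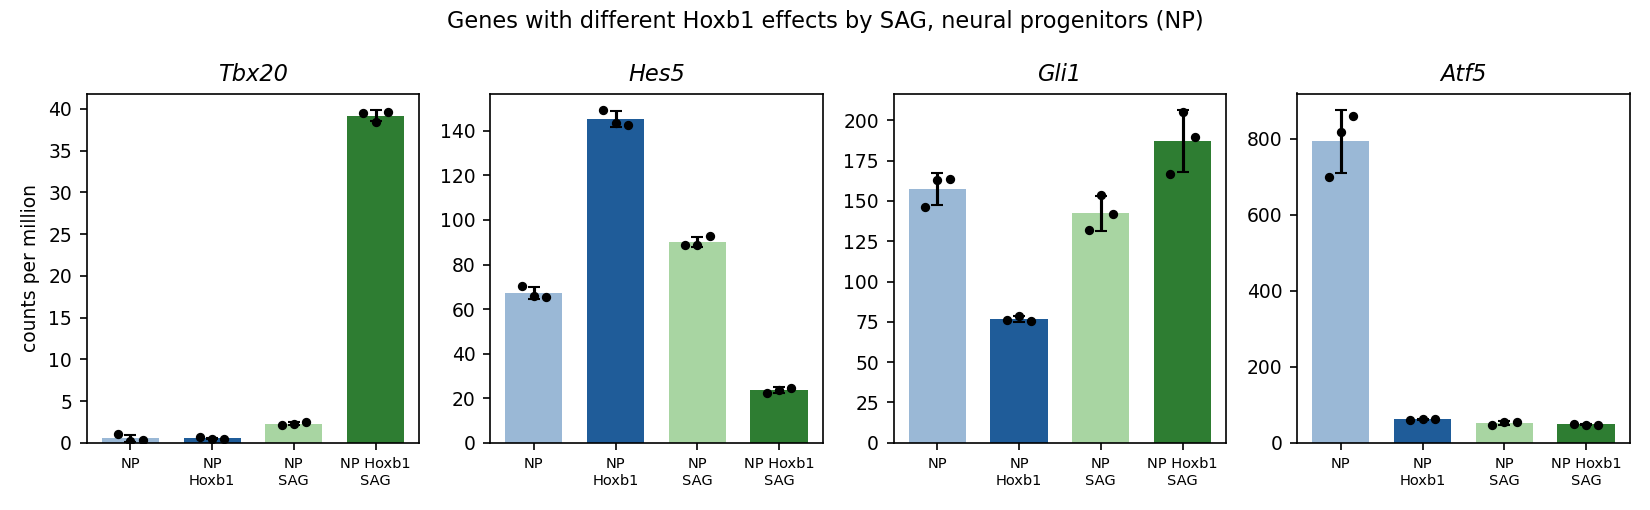
CPM of Tbx20, Hes5, Gli1 and Atf5 in neural progenitors (NP) of 4 groups, with bars for means, error bars for SD of 3 libraries and points for libraries. Tbx20 is at 39.2 CPM with Hoxb1 and SAG and at 0.535 CPM with Hoxb1 alone, Hes5 is higher with Hoxb1 without SAG and lower with SAG, and Atf5 is at 793 CPM in the group with neither and at 61.7 CPM with Hoxb1 alone.

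Cranial and spinal motor neuron genes rose in 9 of 13 and fell in 1 (median log2 change 2.98, adjusted p = 9.21e-06). Hox genes of groups 1 to 4 rose in 7 of 9, Hoxb1 among them (median 2.10, adjusted p = 9.21e-06), those of groups 5 to 9 rose in 9 of 11 and fell in 1 (1.51, 0.00157), and those of groups 10 to 13 rose in 8 of 8 (2.03, 0.000173). Hoxb2 rose from 2.41 ± 0.222 to 75.9 ± 2.25 CPM and Hoxa2 from 1.49 to 4.85 CPM. Hoxc6 rose from 0.905 to 3.19 CPM, Hoxc9 from 0.49 to 1.83 CPM, Hoxa10 from 1.6 to 6.93 CPM and Hoxc10 from 0.763 to 3.18 CPM. Hox cofactors rose in 7 of 9 and fell in 1 (adjusted p = 1.3e-05), led by Meis1 (49.3 ± 0.446 to 148.5 ± 5.54 CPM) and Meis2 (35.5 to 93.7 CPM). Retinoid pathway genes rose in 7 of 11 and fell in 3 (0.000122), with Crabp1 (18.2 to 328.7 CPM) and Crabp2 (32.8 to 192 CPM) the largest. Proneural genes rose in 7 of 11 and fell in 3 (0.00509), lateral and intermediate mesoderm genes rose in 10 of 13 and fell in 1 (0.00157), Tbx20 being in that list too, and p53 targets rose in 10 of 12 and fell in 1 (1.16e-05), as in Eda2r (106.4 to 158.9 CPM) and Plk2 (82.2 to 119.4 CPM). Neural crest genes rose in 7 of 13 and fell in 3 (adjusted p = 0.0432, and adjusted p = 0.0979 with an estimated correlation).

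Forebrain and midbrain genes fell in 12 of 15 and rose in 3 (median log2 change -1.14, adjusted p = 1e-05), Pax8 being among those that rose (0.387 to 6.15 CPM). Hypoxia and glycolysis genes fell in 11 of 12 (median -0.47, adjusted p = 1e-05), as in Slc2a1, a glucose transporter (406 ± 10.7 to 195 ± 3.52 CPM), and Ankrd37 (2.96 to 1.87 CPM). Notch pathway genes fell in 11 of 16 and rose in 2 (median -0.25, 0.00168), glia genes fell in 8 of 11 and rose in 2 (0.00333), and Wnt feedback genes fell in 7 of 11 (0.00237). Neural progenitor genes fell in 9 of 14 and rose in 2 (adjusted p = 0.000493, and adjusted p = 0.056 with an estimated correlation), as in Sox1 (214 ± 5.4 to 103 ± 1.36 CPM). Integrated stress response genes fell in 10 of 15 and rose in 1 (median -0.52, adjusted p = 0.000106, and adjusted p = 0.2 with an estimated correlation). Chac1 was at 44.5 ± 10.7 and 7.06 ± 0.594 CPM and Trib3 at 18.5 and 6.17 CPM. NMP genes fell in 6 of 12 and rose in 1 (adjusted p = 0.0125, and adjusted p = 0.133 with an estimated correlation), as in T (30.8 to 10.3 CPM). TGF-beta and BMP feedback genes fell in 8 of 12 and rose in 3 (adjusted p = 0.0432), and epithelium to mesenchyme genes fell in 7 of 11 and rose in 3 (0.0432), with adjusted p = 0.125 and adjusted p = 0.183 with an estimated correlation.

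Of the 20 called lists with SAG, 14 held with an estimated correlation, the 6 lost being those with such a value above. Adjusted over the list alone, 10 motor neuron, 11 lateral mesoderm and 11 p53 genes rose and 12 Notch, 10 neural progenitor, 9 glia and 7 NMP genes fell, with other counts of called lists unchanged. Median, mean and test differed in sign for 4 lists, none called (presomitic, postmitotic neuron, dorsal neural tube and FGF feedback). Hedgehog feedback was not called (adjusted p = 0.569), with Gli1 rising from 142.5 ± 10.8 to 187 ± 19.3 CPM (adjusted p = 0.00373) and Ptch1 at 625 and 620 CPM (0.828). Nkx2-2 fell from 88.8 ± 1.91 to 56.4 ± 1.24 CPM and Neurog2 from 13.6 to 7.29 CPM. Sox2 (427 and 406 CPM, adjusted p = 0.0659), Tbx6 (1.44 and 1.81 CPM, 0.155) and Cdx2 (0.335 and 0.212 CPM, 0.301) were not called. Sox2 passed with upper-quartile scaling (0.0104), the stricter filter (0.0439), a replicate block (0.0185), and without replicate 1 of the Hoxb1 and SAG group (0.016) or NP replicate 1 (0.0331) or 3 (0.0433). Tbx6 passed without replicate 1 of the Hoxb1 and SAG group (0.0299). Of the other genes with large changes, Gnat3 had 2 counts over the group without and 967 with Hoxb1 (ratio 498, counting interval 137 to 4120), Stab1 rose from 0.392 to 17.8 CPM and Mybpc1 from 1.3 to 69.2 CPM. Hoxb3os, with the same limit on strand, rose from 1.85 to 97.8 CPM. Atp2a3 (36.1 to 3.69 CPM), Corin (37.1 to 6.66 CPM) and Slc6a4, the serotonin transporter (11.1 to 2.12 CPM), fell, Atp2a3 and Slc6a4 lying on chromosome 11.

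The Hoxb1 effect differed between the sets with and without SAG for many genes, with the limit that these sets also differ in library-number range and depth. Effects are compared with their sign, so that a weaker fall counts as a higher effect and a weaker rise as a lower one. Within the set with SAG, X-linked Hprt was at 0.631 CPM without and 15.6 CPM with Hoxb1, and Y-linked Ddx3y at 37.6 and 11.2 CPM. Both genes were chosen after their values were seen. A difference between lines within that set would enter the counts below and was not tested. Notch pathway genes had a lower effect with SAG in 12 of 16 members and a higher one in 2 (median difference -0.999, camera adjusted p = 2.34e-06), the 1 list of this comparison that held with an estimated correlation (0.0212). The effect on Hes5 was lower with SAG than without (log2 difference -3.04, SE 0.0617, adjusted p = 1.38e-33). That on Nrarp, another Notch target, differed by -1.80. The effect on Tbx20 was larger with SAG by 4.04 (SE 0.523, adjusted p = 3.46e-08). Over all genes, 2733 had a higher and 3026 a lower effect with SAG, 420 and 432 of them by at least 2-fold. On chromosome 11 the median difference was -0.11, and 435 of 1363 genes had a lower and 120 a higher effect with SAG.

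**Figure D3:**
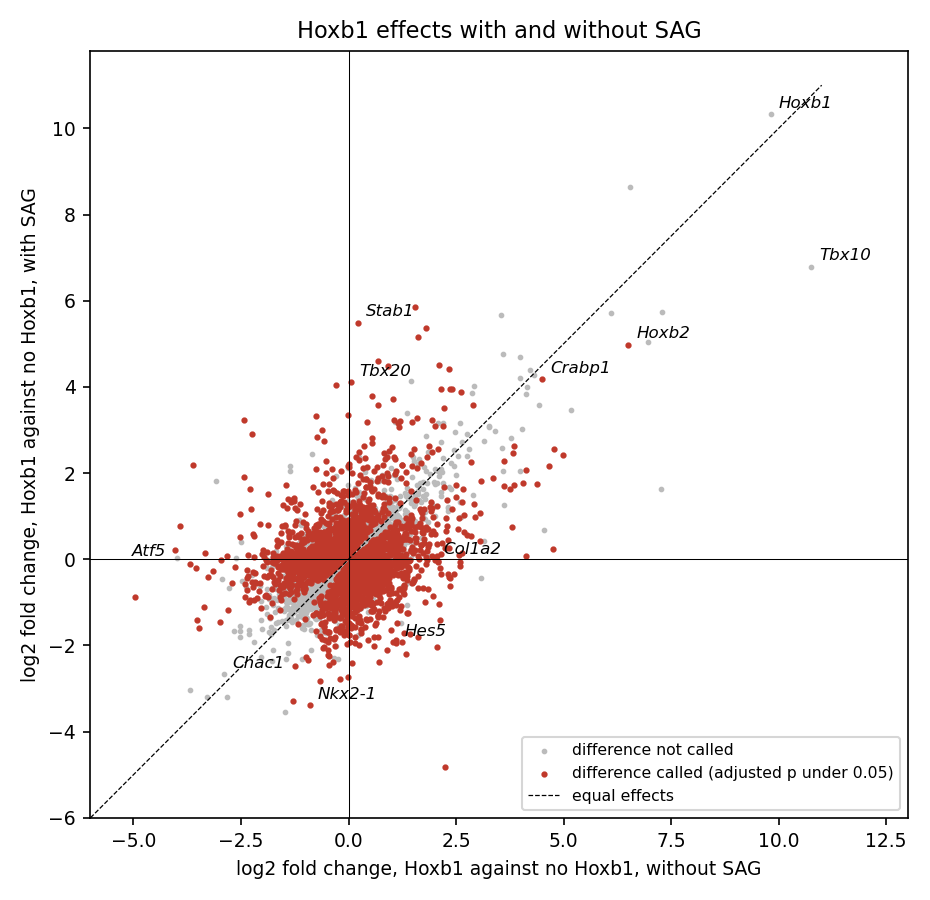
Log2 fold change of 16238 genes for Hoxb1 against no Hoxb1 without SAG (horizontal axis) and with SAG (vertical axis), with red points for genes whose difference was called by edgeR and a dashed line of equal effects. Tbx20 and Stab1 lie above the line, Hes5 and Col1a2 below it and Hoxb1 near it, and 1 gene lies outside the axes.

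Hox genes of groups 5 to 9 had a higher effect with SAG in 8 of 11 members and a lower one in none (adjusted p = 0.00102, and adjusted p = 0.0504 with an estimated correlation), and so did 4 of 8 genes of groups 10 to 13 (adjusted p = 0.000545, and adjusted p = 0.0504 with an estimated correlation). The medians were 1.99 and 2.93, or 1.84 and 2.34 without the 1 and 6 members that had a group with 3 or fewer counts. Named members were Hoxb9 (difference 2.68), Hoxa9 (2.50), Hoxd11 (3.39, with 2 counts over the group with Hoxb1 and no SAG) and Hoxa10 (2.47, adjusted p = 0.00218, and 0.0656 without NP replicate 3). For Hoxb2 and Hoxa2 the effect was lower with SAG (differences -1.52, SE 0.235, and -1.91, SE 0.252), while groups 1 to 4 as a list were not called (adjusted p = 0.0964). Motor neuron genes had a higher effect in 5 of 13 and a lower one in 2 (median 1.28, adjusted p = 0.00707, and adjusted p = 0.0949 with an estimated correlation).

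Integrated stress response genes had a higher effect with SAG in 13 of 15 members and a lower one in none. The median difference was 0.94 (camera adjusted p = 5.1e-10, and adjusted p = 0.13 with an estimated correlation), with Atf5 at 3.57 and Cth, an enzyme of cysteine synthesis, at 1.98. The median Hoxb1 effect on this list was -1.56 without SAG and -0.518 with it, a weaker fall with SAG. For pluripotency genes it was -0.994 and -0.12, for FGF feedback -0.556 and -0.0457, and for hedgehog feedback -0.785 and 0.0703. For ventral genes it was -0.689 and 0.0705, for immediate early genes -0.448 and 0.216, and for p53 targets 0.108 and 0.301. Pluripotency genes were higher in 11 of 14 and lower in 1 (0.92, adjusted p = 2.01e-05, and adjusted p = 0.248 with an estimated correlation), as in Prdm14 (1.98) and Zfp42 (1.16). FGF feedback genes were higher in 8 of 10 and lower in 1 (adjusted p = 0.000495, and adjusted p = 0.243 with an estimated correlation), with Dusp6 at 1.42 and Dusp4 at -0.95. The 4 hedgehog feedback genes were all higher (median 0.95, adjusted p = 0.00168, and adjusted p = 0.169 with an estimated correlation), among them Hhip (1.51), Gli1 (1.43, SE 0.127) and Ptch1 (0.46). Ventral neural tube genes were higher in 5 of 10 and lower in 1 (adjusted p = 0.00933, and adjusted p = 0.153 with an estimated correlation), with Foxa2 at 1.44, Olig2 at 1.05 and Nkx2-2 at 0.88. Immediate early genes were higher in 8 of 10 and lower in 2 (adjusted p = 0.00927, and adjusted p = 0.248 with an estimated correlation), as in Egr3 (2.70) and Fosb (1.77, adjusted p = 0.0203, and 0.0631 without NP replicate 1 or 0.0608 without NP Hoxb1 replicate 3). p53 targets were higher in 7 of 12 and lower in 2 (adjusted p = 0.0429, and adjusted p = 0.306 with an estimated correlation).

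Effects were lower with SAG for neural progenitor genes (9 of 14 lower and 3 higher, adjusted p = 0.00172), as in Sox3 (-1.33), and for hindbrain genes (6 of 9 lower and 2 higher, 0.0202), cell cycle genes (10 of 19 lower and 4 higher, 0.0479), cell cycle inhibitors (6 of 10 lower and 1 higher, 0.0201), glia genes (7 of 11 lower and 2 higher, 0.0201), and hypoxia and glycolysis genes (6 of 12 lower and 1 higher, 0.0183). For these 6 lists adjusted p = 0.132, 0.13, 0.275, 0.132, 0.13 and 0.166 with an estimated correlation. Slc2a1 differed by -1.21, Vegfa by 0.88 and Cdkn2b by -0.98. Adjusted over the list alone, 6 Hox genes of groups 10 to 13, 6 motor neuron genes, 3 hindbrain genes, 2 cell cycle inhibitors and 3 glia genes had a higher effect and 7 hypoxia and 3 p53 genes a lower one, with other counts of called lists unchanged. The largest other differences were in Stab1 (5.28), Cntn2, an axonal adhesion molecule (4.09), Trim66 (4.09, SE 0.758), Slc6a4 (-3.10) and Prelp (-3.01). Sox2 (0.16) and Neurog2 (-1.07) differed, while T (0.23, adjusted p = 0.228), Tbx6 (-0.09, 0.84) and Cdx2 (2.11, SE 0.868, 0.0543) were not called. Cdx2, with 5 to 36 counts per group, passed with limma-voom (0.0101), no filter (0.0496), a replicate block (0.0436), and without replicate 3 of the Hoxb1 and SAG group (0.023) or of the Hoxb1 group (difference 6.44, 0.00141). Median, mean and test differed in sign for 4 lists, none called (presomitic, proneural, forebrain and midbrain, and TGF-beta and BMP).

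**Figure D4:**
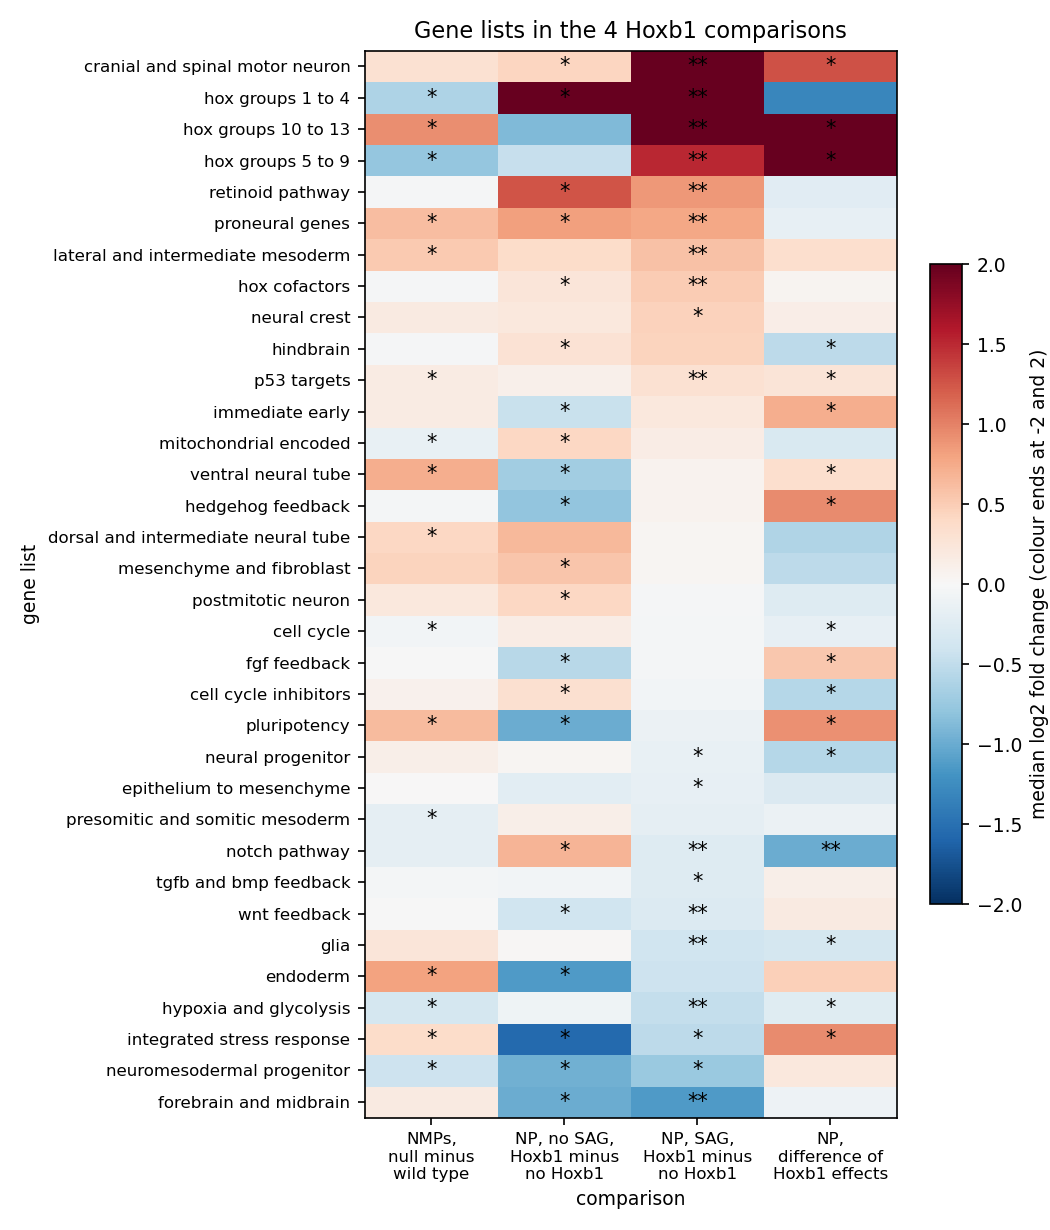
Median log2 fold change (colour, ending at -2 and 2) of the 34 lists called in at least 1 of the 4 Hoxb1 comparisons, with 1 asterisk where camera called the list and 2 where the call held with an estimated correlation. Hox groups 1 to 4 are negative in null NMPs and positive with Hoxb1 in neural progenitors, and the integrated stress response is positive in null NMPs and negative with Hoxb1.

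Both Hoxb1 comparisons of neural progenitors shared more calls than independent calls would. 3180 genes were called in the same direction with and without SAG (1626 expected) and 911 in opposite directions (1628 expected). Among changes of at least 2-fold, 267 went the same way and 29 the opposite way. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.476 and a Spearman rho of 0.341. These comparisons share no libraries. Between null NMPs and neural progenitors with Hoxb1, opposite directions exceeded the expected number, with 1318 genes opposite (984.9 expected) and 1006 the same (986.7 expected) without SAG. With SAG there were 1254 opposite (907.7 expected) and 915 the same (908.1 expected). The correlations across genes were near 0 (r of -0.08 and -0.05, rho of -0.06 and -0.05). At a 2-fold change in both, 41 genes were opposite and 24 the same without SAG (7.125 and 6.797 expected), and 28 opposite and 25 the same with SAG (4.775 and 5.52 expected).

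7 genes were at least 2-fold lower in null NMPs and at least 2-fold higher with Hoxb1 in both neural progenitor comparisons, a set chosen after its values were seen. They are Hoxb1, Hoxb2, Hoxb3, Hoxb4, Car10 and the antisense or intergenic Hox RNAs Hoxb3os and Hoxaas2. Hoxb3 fell from 27.2 ± 2.3 to 9.34 ± 1.3 CPM in null NMPs and rose from 0.735 to 20.4 CPM without SAG and from 2.83 to 16.7 CPM with SAG. Hoxb4 fell from 14.2 ± 1.3 to 5.33 ± 1.6 CPM and rose from 0.442 to 6.3 CPM and from 2.53 to 14 CPM. 4 genes (Fgf18, Chac1, Dmrt1 and Trib3) were higher in null NMPs and lower with Hoxb1 in both comparisons. At the same 2-fold limit, 6 genes were higher in all 3 comparisons and 2 were lower in all 3.

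SAG was compared with no SAG in neural progenitors as a secondary question, with the limit that these groups also differ in library-number range and depth. Without Hoxb1, the ventral gene Nkx2-1 rose 56.4-fold with SAG (1.84 ± 0.382 to 104 ± 4.45 CPM), Nkx2-2 rose 10.7-fold (8.3 ± 1.7 to 88.8 ± 1.91 CPM) and Nkx2-9 rose 28.7-fold. Pax7 and Pax3, dorsal neural tube factors, fell from 13 and 37.6 CPM to 0.0807 and 2.3 CPM. Ptch1, the hedgehog receptor and feedback target, rose from 281 ± 25.1 to 625 ± 10.5 CPM. Gli1 was not called (157.7 CPM without and 142.5 CPM with SAG, adjusted p = 0.161). In some other settings it passed as lower with SAG, with log2 changes of -0.141 to -0.147. These were limma-voom (adjusted p = 0.0298), a fit of the 6 libraries alone (0.0245), all 18 libraries (0.0466), a replicate block (0.000384), and a fit without replicate 1 of the Hoxb1 and SAG group (0.0192). In total 5921 genes were higher and 5889 lower. Pseudogenes were 190 of the 1212 genes at least 2-fold higher and 23 of the 1206 lower, so that most of them lay on the higher side. Among genes with a known type (98.9% of those tested), they were 8.94% of such calls in both directions together, against 6.97% of tested genes. The median change of chromosome 8 genes was -0.24, against -0.08 to 0.1 for autosomes other than 8 and 11.

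Ventral neural tube genes rose in 8 of 10 and fell in 2 (adjusted p = 0.00731, and adjusted p = 0.148 with an estimated correlation), and dorsal and intermediate genes fell in 10 of 16 and rose in 2 (adjusted p = 0.0102, and adjusted p = 0.182 with an estimated correlation). Proneural genes fell in 10 of 11 (adjusted p = 5.38e-05, held with an estimated correlation), mesenchyme and fibroblast genes rose in 11 of 11 (2.56e-06, held), and TGF-beta and BMP feedback genes rose in 11 of 12 (0.000156, held). Examples are Nhlh1 (69.3 to 4.62 CPM), Neurog1 (21.1 to 2.49 CPM), Col3a1 (199.5 to 1306 CPM), Col1a1 (77.1 to 499 CPM), Lefty1, a Nodal antagonist (3.14 to 36.7 CPM), and Id3 (82 to 425 CPM). Postmitotic neuron genes fell in 14 of 17 and rose in 1 (adjusted p = 5.18e-05), FGF feedback genes fell in 10 of 10 (2.56e-06), integrated stress response genes fell in 15 of 15 (1.11e-06), and forebrain and midbrain genes fell in 9 of 15 and rose in 3 (0.0466), with adjusted p = 0.0973, 0.148, 0.159 and 0.328 with an estimated correlation. Cell cycle genes rose in 15 of 19 and fell in 3 (0.000125), lateral mesoderm genes rose in 10 of 13 (0.000717), Hox genes of groups 10 to 13 rose in 7 of 8 (0.0133), immediate early genes rose in 8 of 10 and fell in 1 (0.0136), mitochondrially encoded genes rose in 8 of 10 and fell in 1 (0.0286), and epithelium to mesenchyme genes rose in 8 of 11 and fell in 2 (0.0318). For these 6 lists adjusted p = 0.0973, 0.0791, 0.0973, 0.277, 0.328 and 0.196 with an estimated correlation. Adjusted over the list alone, the counts of called lists in this comparison were unchanged. Blood and endothelium genes were called by camera in none of the 6 comparisons (5 rose and 4 fell here, adjusted p = 0.839).

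With Hoxb1 present, SAG raised Tbx20 from 0.535 ± 0.0917 to 39.2 ± 0.654 CPM, Foxa2, a floor plate factor, from 4.09 ± 0.592 to 100.2 ± 2.18 CPM and Phox2a from 3.92 to 34.5 CPM. Pax6, a neural progenitor factor, fell from 112 ± 3.19 to 14.3 ± 0.49 CPM. Here 5915 genes were higher and 5811 lower, with 175 pseudogenes at least 2-fold higher and 16 lower, and chromosome medians of -0.15 for 8 and -0.17 for 11. The 4 hedgehog feedback genes all rose (adjusted p = 0.00203, and adjusted p = 0.155 with an estimated correlation). Gli1 was at 76.7 and 187 CPM and Ptch1 at 202 and 620 CPM. Motor neuron genes rose in 12 of 13 and fell in 1 (adjusted p = 0.000207), ventral genes rose in 8 of 10 (0.000204), Hox genes of groups 5 to 9 rose in 11 of 11 (0.000919) and of groups 10 to 13 in 8 of 8 (0.000273, median 5.97, or 4.38 with members of 3 or fewer counts at their bound), and lateral mesoderm genes rose in 12 of 13 (0.000204). Hoxa11 and Hoxd11 had 1 and 2 counts over the group without SAG (ratios 143, counting interval 25.5 to 5680, and 97.5, 26.8 to 808). Neural progenitor genes fell in 13 of 14 and rose in 1 (6.25e-05), proneural genes fell in 10 of 11 and rose in 1 (0.000163), Notch genes fell in 12 of 16 and rose in 1 (0.000759), and TGF-beta and BMP feedback genes rose in 10 of 12 and fell in 1 (0.000919). These 9 lists from motor neuron to TGF-beta and BMP held with an estimated correlation. Of the other called lists, pluripotency genes rose in 14 of 14 (adjusted p = 4.04e-05, and adjusted p = 0.178 with an estimated correlation) and dorsal neural tube genes fell in 12 of 16 and rose in 4 (adjusted p = 0.00284, and adjusted p = 0.113 with an estimated correlation). Postmitotic neuron genes fell in 14 of 17 and rose in 3 (adjusted p = 0.000253), FGF feedback genes fell in 9 of 10 (0.000221), forebrain and midbrain genes fell in 11 of 15 and rose in 3 (0.012), hindbrain genes fell in 8 of 9 and rose in 1 (0.0467), and glia genes fell in 7 of 11 and rose in 3 (0.026). For these 5 lists adjusted p = 0.099, 0.168, 0.199, 0.113 and 0.099 with an estimated correlation. Mesenchyme and fibroblast genes rose in 10 of 11 and fell in 1 (0.00033), immediate early genes rose in 9 of 10 (0.000459), and cell cycle genes rose in 14 of 19 and fell in 4 (0.00129), with adjusted p = 0.0564, 0.113 and 0.102 with an estimated correlation. Integrated stress response genes fell in 9 of 15 and rose in 1 (adjusted p = 0.0216, and adjusted p = 0.406 with an estimated correlation). Adjusted over the list alone, 8 of these 15 fell, with the other counts given here unchanged. The responses to SAG with and without Hoxb1 shared 9007 calls in the same direction and 585 in opposite directions (4264 expected for each), with r of 0.779 and rho of 0.783 across genes.

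**Figure D5:**
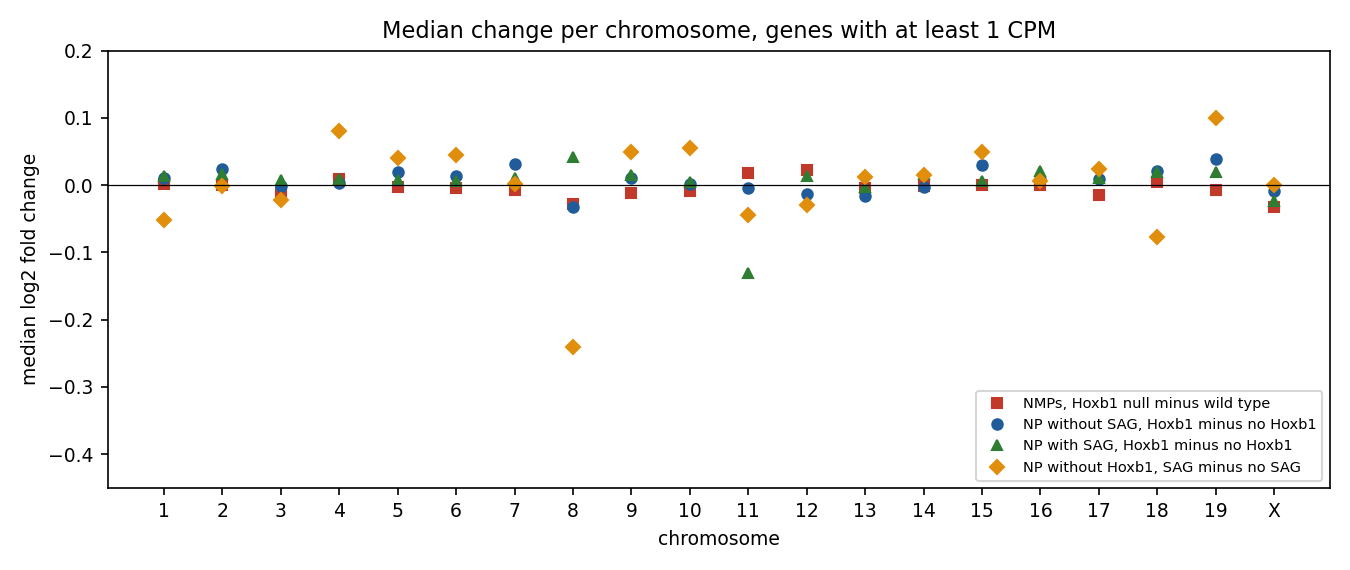
Median log2 fold change per chromosome (autosomes and X, genes with a mean of at least 1 CPM in at least 1 of the groups compared) in 4 comparisons, shown by symbol. Chromosome 11 lies at -0.13 for Hoxb1 with SAG and chromosome 8 at -0.24 for SAG without Hoxb1.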

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

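The tests of the Y-linked genes, of the integrated stress response, and of the Hoxb genes against other clusters and in neural progenitors were chosen after the results were seen.

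The genes in this part had a Hoxb1 effect that differed between the neural progenitors with and without SAG by a test of the difference of the effects (edgeR, n = 3 in each of 4 groups). The lists were tested by camera, and 1 of the 17 called lists, the Notch pathway, held with an estimated correlation. The libraries with and without SAG are separate sets, so that the difference is not separated from the library set. Nor is it separated from a possible difference between lines within a set. The effect, taken with its sign, was higher with SAG for 2733 genes and lower for 3026. In NMPs no second set of groups exists for such a test.

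Among motor neuron and neuronal genes, the log2 difference was 4.04 for Tbx20 (0.06 without SAG and 4.10 with it), 2.02 for Nefl (1.14 and 3.16), 1.29 for Neurod4 (2.23 and 3.52), -0.29 for Ina (1.15 and 0.86) and -1.07 for Neurog2 (0.17 and -0.90). Cntn2 had a difference of 4.09 (-0.77 and 3.33). The motor neuron list had a median of 1.28.

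Among Hox genes and cofactors, the difference was 3.39 for Hoxd11 (SE 0.973, with 2 counts over the group with Hoxb1 and no SAG, so that its size is uncertain), 2.68 for Hoxb9, 2.50 for Hoxa9, 2.47 for Hoxa10, 2.21 for Hoxc10, 1.29 for Hoxc6, 0.15 for Meis1, -1.52 for Hoxb2 and -1.91 for Hoxa2. The medians were 1.99 for Hox groups 5 to 9 and 2.93 for groups 10 to 13, over all tested members of these lists. For the retinoic acid binding proteins Crabp2 and Crabp1, which rose with Hoxb1 in both sets, it was 0.48 and -0.32. Hindbrain genes had a median of -0.53.

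Among Notch and neural progenitor genes, the difference was -3.04 for Hes5 (1.11 and -1.93), -1.80 for Nrarp (1.01 and -0.79), -1.66 for Hey2, -1.33 for Sox3, -0.61 for Sox1 and 0.16 for Sox2. The list medians were -0.999 for the Notch pathway, -0.58 for neural progenitors and -0.35 for glia.

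Among hedgehog, ventral and forebrain genes, the difference was 1.51 for Hhip (-1.35 and 0.15), 1.43 for Gli1 (-1.04 and 0.39), 0.46 for Ptch1, 1.44 for Foxa2, 1.05 for Olig2, 0.88 for Nkx2-2, 1.60 for Pax8, 1.33 for Six6 and -2.47 for Nkx2-1. The hedgehog feedback list had a median of 0.95 and the ventral neural tube list of 0.34.

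Among signalling and early lineage genes, the difference was 1.42 for Dusp6, 0.60 for Spry1, -0.95 for Dusp4, 1.2 for Fgf17, 1.98 for Prdm14, 1.16 for Zfp42, 1.02 for Klf2, 2.70 for Egr3 and 1.77 for Fosb. The list medians were 0.54 for FGF feedback, 0.92 for pluripotency and 0.73 for immediate early genes.

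Among stress, metabolic and cell cycle genes, the difference was 3.57 for Atf5 (-3.68 and -0.12), 1.98 for Cth, 1.88 for Trib3, 1.52 for Slc7a11, 0.88 for Vegfa, -1.21 for Slc2a1, 0.37 for Eda2r, 0.35 for Plk2 and -0.98 for Cdkn2b. The list medians were 0.94 for the integrated stress response, 0.26 for p53 targets, -0.24 for hypoxia and glycolysis, -0.16 for the cell cycle and -0.58 for its inhibitors. Of the remaining genes, the difference was 5.28 for Stab1 (0.22 and 5.49), 4.09 for Trim66 (-4.96 and -0.87), -2.03 for Col1a2 (2.00 and -0.03), -1.23 for Corin, -2 for Atp2a3, -3.01 for Prelp and -3.10 for Slc6a4. Atp2a3 and Slc6a4 lie on chromosome 11, whose median difference was -0.11.

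In the cultures with SAG, the Y-linked Eif2s3y, Uty and Ddx3y, seen after the values were known, were lower with Hoxb1 (43.3 to 14.8, 24.4 to 8.36 and 37.6 to 11.2 CPM). The median log2 change of the 4 tested Y-linked genes of at least 10 CPM was no nearer 0 than -1.55 in 4 other fits. These used RLE factors, upper-quartile factors, DESeq2 and all 18 libraries. The choice among them thus does not account for the fall. They shifted the changes of all genes by a median of only -0.025 to -0.0032, so that a larger error of scaling was not tested. Without SAG the median of the same 4 Y-linked genes was 0.00972, which argues against an action of Hoxb1 or doxycycline alike in every culture. Cells of another chromosome content, or of another line, in the cultures with Hoxb1 and SAG may be a source. The changes ranged over 2.28, and over 0.201 without Gm47283. Gm47283 (log2 change 0.531) lies at 90784738 on the Y chromosome, apart from Eif2s3y, Uty and Ddx3y (1010543 to 1286613). Those 3 genes changed by -1.55, -1.55 and -1.75. Below 10 CPM, Uba1y (-1.06) and Kdm5d (-0.589) were lower too, Kdm5d also without SAG (-0.65). The wide range thus rests on 1 gene and does not decide against this source, which stays open. No other biological explanation was tested.

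In null NMPs, the 8 tested Hoxb genes of groups 2 to 9 fell. The 39 other tested genes within 1 Mb of Hoxb1 had a median log2 change of 0.021 (6 higher and 5 lower), which argues against a change over that whole region, but Skap1, the nearest tested gene past Hoxb1, had the lowest value (-1.16, adjusted p = 0.000413), so that a change reaching just past the cluster stays open. The Hoxb median lay below that of the other clusters (difference -1.04), so that the fall was not alike over the clusters. This split was made after these values were seen and repeats them. A culture less advanced in Hox expression therefore stays open. Hoxb2, Hoxb3 and Hoxb4 rose with Hoxb1 in neural progenitors (lowest log2 change 2.47), so an action of Hoxb1 on its neighbours may contribute, while an effect in cis of the altered allele in NMPs stays open.

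With Hoxb1, the integrated stress response list was lower in neural progenitors at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.0515 without SAG and 0.2 with SAG). Doxycycline stress on mitochondria, as posed, would raise these genes where doxycycline was given. They were lower there in 15 of 15 members without SAG (median -1.56) and in 10 of 15 with SAG, with 1 higher (median -0.518). That direction is the pattern that prompted the test, so that it adds no evidence on doxycycline, whose actions stay open. The test of a stressed culture without Hoxb1 in the set without SAG (median -0.518 with SAG) repeats the fall that prompted it and excludes nothing, so that it stays open. The group with neither Hoxb1 nor SAG had the higher values, since the list also fell in 15 of 15 members with SAG in cultures without Hoxb1 (median -1.61, adjusted p = 0.159 with an estimated correlation) and Atf5 was at 793 CPM in that group, against 46.5 to 63.4 CPM in the libraries of the other 3 groups of neural progenitors. Medium or density may have differed between cultures with and without Hoxb1 (median of -1.56 without SAG), which cannot be told apart from Hoxb1, since each culture holds 1 combination. Hoxb1 itself stays open as an untested biological cause.

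Other splits of the libraries were fitted in the same way. With 10 splits of 6 libraries, where a share under 0.05 cannot be reached, 1 split, the real one, gave as many genes in each of 5 comparisons. The real counts were 4327 for null NMPs, 7499 and 7045 for Hoxb1 without and with SAG, and 11810 and 11726 for SAG without and with Hoxb1, and the highest other count by edgeR was 0 in each. At an unadjusted p under 0.05 the highest other counts were 516, 659, 1320, 337 and 294. For the difference of effects, 2 of 100 splits, the real one among them, gave as many genes as the 5759 of the real one. These splits also break up the Hoxb1 effect within each SAG set. They therefore do not test equal effects with and without SAG, and chance stays undecided. The highest other, with 8518 genes, exchanges the Hoxb1 labels in 1 SAG set and so tests the sum of both effects, and without such an exchange the highest was 3553.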

How the results depend on the processing

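The count without genes of chromosomes 8, 11 and Y was chosen after the data were seen.

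Of 230 results for named genes, 216 kept their side of the threshold, and their direction where called, in every alternative run that tested them. Of 4480 checks 4424 were the same, 36 weaker, 20 stronger and 0 reversed. A gene that a run did not keep was not checked there, and the stricter filter gave 185 same, 1 stronger and 2 weaker. The added fold limit and the limit of an adjusted p under 0.01 were not applied to single genes. Many of these genes were named because they were called with large changes, so that this stability follows in part from the rule. RLE factors changed no call among these 230. In NMPs, DESeq2 called 1426 genes higher, against 2244 with edgeR, and the cause was not tested. A limit of an adjusted p under 0.01 left 1417 higher and 1305 lower there, by its own construction.

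An added limit of 2-fold lowered every count of called genes, by construction. It left 326 higher and 104 lower in null NMPs, 462 and 493 for Hoxb1 without SAG, 430 and 385 with SAG, 420 and 432 for the difference of effects, and 1212 and 1206, and 1232 and 1241, for SAG without and with Hoxb1.

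Leaving out 1 library moved no count by over 1.5 times. In NMPs the ranges were 1512 to 2514 higher and 1416 to 2583 lower, and for Hoxb1 without SAG 3397 to 3866 and 3209 to 3786. With SAG they were 2818 to 3568 and 3115 to 3782, for the difference of effects 2451 to 2822 and 2717 to 3023, and for SAG 5510 to 6040 and 5702 to 6049 without Hoxb1 and 5553 to 6075 and 5534 to 5983 with it. Hoxb2, higher with SAG in cultures with Hoxb1, lost that call with DESeq2 (adjusted p = 0.0929) and without NP Hoxb1 replicate 2 (0.108) or 3 (0.0565).

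Residuals of libraries with the same replicate number correlated between -0.05 and 0.16, and the numbers did not pair the libraries throughout any pair of groups. Between the groups with SAG, numbers 1, 2 and 3 gave 0.16, 0.13 and 0.0017. Numbers 1 and 2 crossed gave -0.13 and -0.15 there, so that a partial pairing in that set stays open. With a replicate block, 2181 genes were higher and 2047 lower in null NMPs, 4148 and 3766 for Hoxb1 without SAG, 3898 and 3859 with SAG, 3053 and 3286 for the difference of effects, and 5953 and 5927, and 5945 and 5850, for SAG. Camera with this block called 17, 20, 18, 15, 14 and 20 lists in the 6 comparisons, sharing 16, 20, 17, 15, 14 and 20 with the calls without it.

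With an estimated correlation camera called 0 lists in null NMPs, 0 for Hoxb1 without SAG and 14 with SAG, 1 for the difference of effects, and 3 and 9 for SAG. At the preset correlation it called 16, 21, 20, 17, 15 and 21, and fry, which does not compare a list with other genes, called 25, 35, 31, 29, 33 and 34. Among lists that camera did not call, fry called 4 in the reverse direction. They were dorsal and intermediate neural tube genes for Hoxb1 without SAG (fry adjusted p = 0.00108), neural crest genes in the difference of effects (0.0181), and retinoid pathway genes for SAG without Hoxb1 (4.02e-06) and with it (2.29e-06). Further lists called by neither test also differed in direction, as did hindbrain genes in null NMPs (fry adjusted p = 0.652). The cause was not tested.

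Upper-quartile factors raised the share of higher genes among called genes from 51.9% to 58.2% in null NMPs and lowered it from 49.4% to 41.3% for Hoxb1 with SAG. For Hoxb1 without SAG they lowered it from 52.1% to 46.3%, so that the side with more called genes changed there. Without chromosomes 8, 11 and Y, 1934 genes were higher and 1811 lower in null NMPs and 3406 and 3017 for Hoxb1 without SAG. Depth limits genes with few counts, such as Cdx2 and Hox genes of groups 10 to 13 in neural progenitors.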

Other observations

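The genes of this part were chosen after their values were seen.

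Beside the 7 genes lower in null NMPs and higher with Hoxb1, 6 genes were at least 2-fold higher in all 3 Hoxb1 comparisons. Among these were Lhx3, a motor neuron factor (log2 changes 1.41 in null NMPs, 3.4 without SAG and 2.98 with SAG, at a mean of 1.09 CPM or less in each group), Chrna3, an acetylcholine receptor subunit (1.02, 1.49 and 3.20), the BMP antagonist Grem1 (1.26, 2.40 and 3.96), Angpt2 (1.10, 2.67 and 1.62) and Postn (1.38, 1.73 and 1.62). Noto, a factor of the node and notochord (-1.22, -3.68 and -3.03), and A2m (-1.14, -1.17 and -1.49) were at least 2-fold lower in all 3.

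Hprt, an X-linked enzyme of purine salvage, stood at 0.631 ± 0.022 CPM with SAG and 15.6 ± 1.4 CPM with Hoxb1 and SAG. It stood at 4.16 ± 0.41 CPM without Hoxb1 or SAG, 6.73 ± 0.95 CPM with Hoxb1, and 95.7 ± 2.3 and 106 ± 5.2 CPM in wild-type and null NMPs. Whether these cultures came from 1 line or clone is not given in the sources used here. Meg3, lower in null NMPs, was not called for Hoxb1 in neural progenitors (933 and 960 CPM without SAG, 482 and 485 CPM with SAG). Dlk1, a paternally expressed gene of the same imprinted region, stood at 9.95 and 8.67 CPM in wild-type and null NMPs (adjusted p = 0.159). Xist was at 0.39 ± 0.16 CPM in wild-type and 1.39 ± 0.32 CPM in null NMPs. Y-linked Eif2s3y was at 22 ± 0.65 and 53.8 ± 3.5 CPM and Ddx3y at 28.1 ± 0.74 and 47.8 ± 2.7 CPM in these groups. Whether Meg3, Xist and these Y-linked genes differ in NMPs through Hoxb1 or through the line was not tested.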
